A study of Mus musculus with 117 samples.

How the data were processed

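The series holds 117 mouse samples: 28 RNA-seq libraries, 78 ChIP-seq samples, of which 64 are immunoprecipitations and 14 inputs, and 11 ATAC-seq samples. The inputs and the ATAC-seq samples are not analysed here. Ubc9 is the single E2 enzyme that conjugates SUMO to proteins, and it was depleted by a short hairpin RNA (shUbc9, beside a control hairpin, shCtrl) or, in ES cells, by a small interfering RNA (siUbc9, beside siCtrl). The cells were embryonic fibroblasts (MEF) of embryonic day 13.5, MEF expressing the reprogramming factors Oct4, Klf4, Sox2 and Myc for 4 days (D4) or 7 days (D7), induced pluripotent cells (iPS) and ES cells. The labels do not say whether replicates came from separate cultures or animals, so the p-values measure only the spread between these libraries.

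Per the file headers, the RNA table has 1 column per library, and the authors deposited it as a read count per gene, by Entrez identifier, or per repeat family, with no normalization. All 28 columns were matched to their labels, with 0 left over. The submitters' processing notes name STAR 2.5.0a, featureCounts and DESeq2, with build mm9. Whether reads mapping to several places were counted, the strand setting and the annotation version are not given in the sources used here. The table held 26301 genes and 799 repeat families. Gene symbols came from a name table of assembly GRCm38, used for names alone, in which 24191 identifiers matched and 2110 did not. The cells at D4 and D7 and the iPS lines carried the reprogramming cassette, so counts of Pou5f1, Sox2, Klf4 and Myc may include its transcripts, which could not be told apart.

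For ChIP-seq the authors deposited 32 peak lists, each made from both replicates of 1 antibody and condition, with positions on mm9 and a score per peak. The authors' score was tested on the values and is 10 times another column of the same file, rounded down. Only its ranks within a list were used here. The submitters' processing notes name Bowtie, bedtools 2.19.1 and MACS2, and Bowtie2 for the H3K9me3 samples of siCtrl and siUbc9 ES cells. The peak threshold is not given in the sources used here. The lists held 4468 to 37505 peaks after repeated lines were removed, 5683 of them from H3K27me3 in MEF and 1752 from H3K27me3 in ES cells.

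Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. In each comparison, genes were kept by filterByExpr with its minimum count of 10, libraries were scaled by TMM, and the edgeR quasi-likelihood test was applied, two-sided, with Benjamini-Hochberg adjustment over the genes tested. A gene was called changed at an adjusted p under 0.05. Group levels are given as CPM, counts scaled to a common effective library size, as mean ± SD, and log2 CPM values for projections used a prior count of 2. Fold changes are those fitted by the model. Where every library of a group was at 0, a bound was computed against a floor of 3 counts over the group. Floors and intervals cover counting error only. DESeq2 1.42.0 was run beside it.

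The comparisons were depletion against control in MEF, D4, D7, iPS and ES cells, 4 comparisons between control groups (ES with MEF, D4 with MEF, D7 with D4, iPS with ES), and 3 tests of whether the response to depletion differed between states (ES and MEF, D7 and D4, iPS and ES), 12 in all. A total of 27 gene lists with 673 members, of which 666 were in the table, covered pathways, lineages and, in 6 lists, markers of other cell types that the cultures could hold. Lists with at least 5 tested members were tested by camera with its preset correlation of 0.01, adjusted over the lists of 1 comparison. Beside it stand camera with an estimated correlation, fry, and the number of members changed when adjusted over the list alone. The fry p-value tests whether a list's genes move on balance one way, its mixed p-value whether they change in either direction, and neither compares the list with other genes.

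Somatic genes were those at least 4-fold higher in MEF shCtrl than in ES siCtrl, and pluripotent genes the reverse, each with an adjusted p under 0.05. They were tested by camera in D4, D7 and iPS, whose libraries do not enter their definition. Each library was also placed on the line from the mean of MEF shCtrl (0%) to the mean of ES siCtrl (100%) by projecting the log2 CPM of these genes, and groups were compared by a two-sided exact permutation test. Repeat families were tested with the library sizes and TMM factors of the genes.

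The genes named in the text followed a rule. They are the 10 largest rises and 10 largest falls per depletion comparison among called genes with a mean of at least 1 CPM and no overlap between the libraries of the compared groups. Symbols of predicted genes and pseudogenes were counted but not named, and some genes that the rule selected are not reported here. For each list that passed or had 3 or more changed members, up to 4 members were added, the 2 rises and 2 falls with the smallest p. For other comparisons the rule took 5 rises and 5 falls, and for genes changed the same way in at least 4 of the 5 depletion comparisons up to 10. Lists, comparisons, tests, this rule and most alternatives were fixed before the data were examined. The tests of repeat families were not among those fixed.

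Peak overlaps were computed in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1, and plots drawn with matplotlib 3.10.9. Peaks overlapped when they shared at least 1 bp. Shares carry 95% Wilson intervals, and 100 circular shifts along each chromosome gave the overlap expected by chance. As each list merges its replicates, there is no test across replicates for peaks, and tests over peaks treat peaks as units. The split of SUMO peaks into shared and cell-type-specific ones, the strongest SUMO peaks, and the loss of H3K27ac by SUMO overlap were added after the lists had been seen. Genes near SUMO peaks were not analysed, since no gene coordinates on mm9 were used here.

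The RNA procedure was tested on simulated data with the counts, group sizes and spread of the depletion comparisons and of the difference between ES and MEF. The other comparisons were not simulated. Few genes were changed in each simulation, far fewer than were called at D4, D7 and in ES cells, so the rates need not hold there. Of genes changed 2-fold, it recovered 98.2% with the design of MEF, 100% with that of D4, 84.2% with that of D7, 100% with that of ES cells, 91.7% for the difference between ES and MEF, and 0% with that of iPS. Of genes changed 1.5-fold it recovered 90.4%, 84.4%, 52.1%, 73.0%, 62.5% and 0% in the same order, and of genes changed 4-fold 100%, 100%, 100%, 100%, 98.7% and 0%. The share of calls that were false was 9.48% for MEF, 6.40% for D4, 10.3% for D7, 8.50% for ES cells and 8.60% for the difference between ES and MEF. The overlap functions were checked against a direct count on 20 simulated pairs of lists, with 0 wrong answers of 3200.

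The alternatives tried were DESeq2 in place of edgeR, DESeq2 size factors in place of TMM, no filter on low counts, a replicate block, 1 fit of all RNA libraries, each library left out in turn, other fold minimums for the signatures, other list tests, stricter peak lists and stricter overlap. Scaling by library size alone, other scalings of repeat families, and leaving out both shallow libraries at once were added after seeing the data.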

Results

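RNA was measured in 10 groups of mouse cells, with 3 libraries each except for MEF shUbc9 and iPS shCtrl, which had 2. Peak lists covered the SUMO proteins SUMO-1 and SUMO-2 and 5 histone marks in MEF and ES cells, the same marks and the factors Oct4, Klf4 and Sox2 at D4 with and without Ubc9 depletion, and H3K9me3 in ES cells with and without it. Counts in genes ranged from 11.4 to 58.8 M per library, and repeat families held 7.22% to 24.8% of all counts. In replicate order, gene counts were 39.9, 54.0 and 44.9 M in MEF shCtrl, 45.2 and 46.4 M in MEF shUbc9, 25.1, 46.7 and 38.3 M in D4 shCtrl, and 41.2, 56.6 and 35.9 M in D4 shUbc9. They were 45.5, 35.2 and 19.8 M in D7 shCtrl, 34.7, 37.6 and 42.3 M in D7 shUbc9, 25.5 and 42.0 M in iPS shCtrl, and 34.7, 11.4 and 58.8 M in iPS shUbc9. In ES cells they were 54.0, 46.3 and 48.8 M for siCtrl and 17.4, 53.2 and 44.5 M for siUbc9.

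The comparison of ES with MEF controls described how the 2 ends of the course differed. The ES cells had received a small interfering RNA and the MEF a hairpin, so differences of cell source and delivery are included. Hprt was at 0.773 CPM in ES siCtrl, 72.3 CPM in MEF shCtrl and 143 CPM in iPS shCtrl, so not every difference was shared by iPS cells. Lin28a, an RNA-binding protein of pluripotent cells, was at 0 in MEF and at 693 ± 38.8 CPM in ES cells (SD, n = 3 each), at least 29100-fold higher against a floor of 3 counts over the group. The pluripotency factor Sall4 was at least 23500-fold higher at 559 ± 51.7 CPM, and Fgf4, the growth factor that ES cells secrete, at least 10800-fold higher at 257 ± 19.4 CPM. Zfp936 and Dppa4 were at least 12200-fold and 7940-fold higher. The interferon-stimulated gene Ifit3 was at 883 ± 122 CPM in MEF and at 0.0541 ± 0.00985 CPM in ES cells, and Ifi44 and Trim12a were at least 17200-fold and 3350-fold lower in ES cells. The edgeR test called 16418 of 18149 genes, 8653 higher and 7765 lower in ES cells, and the median log2 fold change of all tested genes was 0.13, or 0.27 with library sizes alone.

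MEF expressing the reprogramming factors for 4 days under the control hairpin were compared with control MEF. Aldh3a1, an aldehyde dehydrogenase of epithelia, rose from 1.04 ± 0.381 to 374 ± 21.4 CPM (367-fold, adjusted p = 1.64e-10, n = 3 each). The intestinal homeobox gene Isx and the membrane protein gene Mall were at 0 in MEF and at least 199-fold and 168-fold higher at D4. The stress-response gene Trib3 fell 56.8-fold and the connexin gene Gjb2 fell 52.7-fold. Of 16715 genes, 11152 were called, 5558 higher and 5594 lower at D4. With library sizes alone the share higher was 62.2% instead of 49.8%, with a median log2 fold change of 0.10.

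Between D4 and D7 under the control hairpin, Tdgf1, a co-receptor for Nodal found in pluripotent cells, rose from 0.112 ± 0.0243 to 2.002 ± 1.20 CPM (19.1-fold, adjusted p = 0.00195). Cldn4, a tight junction protein of epithelia, rose from 0.394 ± 0.0522 to 5.29 ± 2.65 CPM (14.1-fold, adjusted p = 0.000724). Col10a1, a cartilage collagen, fell from 18.3 ± 1.64 to 5.95 ± 0.798 CPM (3.04-fold, adjusted p = 0.000218). The interferon-stimulated gene Mx1 fell from 66.6 ± 26.4 to 16.1 ± 10.3 CPM (adjusted p = 0.021), a call that was lost without D4 shCtrl replicate 1 (adjusted p = 0.0709) or D7 shCtrl replicate 1 (adjusted p = 0.091). In all 3057 of 16792 genes were called, 1772 higher and 1285 lower, with n = 3 in each group. The count was 1803, 1710 and 1669 without D4 shCtrl replicate 1, D4 shCtrl replicate 3 and D7 shCtrl replicate 1, and with library sizes alone 39.4% of called genes were higher instead of 58.0%.

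The iPS controls were compared with ES controls as 2 pluripotent states. Trim12a and Ubd, a ubiquitin-like protein induced by interferon, were at 0 in ES siCtrl and at 9.62 ± 0.153 and 4.84 ± 0.0679 CPM in iPS shCtrl (n = 2), at least 472-fold and 237-fold higher. Cysltr2, Gbp2b and Pip were at 0 in iPS shCtrl and at least 179-fold, 172-fold and 154-fold lower. Adgre1, a macrophage surface protein, was at 6.37 ± 7.86 CPM in iPS shCtrl, so the 2 libraries differed widely. Of 18108 genes, 9655 were called, 4950 higher and 4705 lower in iPS. The median log2 fold change of all genes was -0.01, or 0.12 with library sizes alone.

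Depletion of Ubc9 in MEF tested what SUMO does in the somatic state. Saa3, an acute-phase protein, rose from 4.40 ± 0.948 CPM (n = 3) to 35.9 ± 4.27 CPM (n = 2), or 8.08-fold (adjusted p = 1.65e-05). Lcn2, a secreted siderophore-binding protein, rose from 0.183 ± 0.0881 to 4.21 ± 0.0540 CPM (21.9-fold, adjusted p = 3.87e-05), and haptoglobin, Hp, from 6.82 ± 1.01 to 29.9 ± 4.90 CPM (adjusted p = 4.76e-05). Marco, a scavenger receptor of macrophages, was at 0 in controls and at 3.603 ± 0.578 CPM after depletion, at least 151-fold higher (adjusted p = 9.86e-05). The cartilage matrix genes Col2a1 and Acan fell, from 106 ± 6.90 to 46.4 ± 1.27 CPM (2.29-fold, adjusted p = 4.76e-05) and from 11.6 ± 0.571 to 4.98 ± 0.0622 CPM (2.33-fold, adjusted p = 0.000256).

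Among gene lists in MEF, 14 of 21 immune cell genes rose and 0 fell (17 changed when adjusted over the list alone), with a median log2 fold change of 0.61, and camera gave an adjusted p = 2.6e-16, but an adjusted p = 0.46 with an estimated correlation. Its members Itgam, an integrin of myeloid cells, and Ctss, a lysosomal protease, rose from 3.64 ± 0.844 to 9.88 ± 0.168 CPM and from 19.7 ± 2.42 to 32.7 ± 2.72 CPM. Of 35 cell cycle genes 0 rose and 9 fell (22 over the list alone, median -0.22, adjusted p = 6.8e-11, and 0.46 with an estimated correlation). Of 20 TGF-beta and SMAD targets 3 fell and 0 rose (7 over the list alone, median -0.15), among them Bmp4, from 92.7 ± 3.94 to 71.3 ± 2.06 CPM, with an adjusted p = 0.000404, and 0.46 with an estimated correlation. Of 23 cholesterol biosynthesis genes 5 rose (9 over the list alone, median 0.12, adjusted p = 4.2e-05, and 0.46 with an estimated correlation). Of 39 interferon response genes 2 rose (2 over the list alone), with an adjusted p = 0.0133, lost without shCtrl replicate 2 (0.276) or shUbc9 replicate 3 (0.748), and 0.773 with an estimated correlation. The fibroblast list, with 7 of 49 members higher and 3 lower (13 over the list alone), did not pass (adjusted p = 0.497). Of the lists in MEF, 5 of 25 passed, and 8 did without shUbc9 replicate 1.

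The test in MEF called 984 of 16287 genes, 624 higher and 360 lower, of which 83 and 14 changed at least 2-fold. The count was 1717 without shCtrl replicate 2 (842 higher and 875 lower, so that the majority direction turned), 398 without shCtrl replicate 3, 330 without shUbc9 replicate 1 and 266 without shUbc9 replicate 3, the last 2 fits having a single depleted library, whose spread was taken from the controls. With library sizes alone 52.1% of called genes were higher instead of 63.4%, and a fit of all RNA libraries with a shared spread called 42 genes, 36 higher and 6 lower.

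Depletion at D4 asked how SUMO acts on cells at an early stage of reprogramming. Krt6a, a keratin of stressed epidermis, rose from 1.80 ± 0.227 to 67.3 ± 6.01 CPM (36.2-fold, adjusted p = 7.27e-08, n = 3 in each group). Akr1c18, a steroid-metabolising reductase, rose from 0.375 ± 0.0995 to 15.2 ± 2.75 CPM (40.3-fold, adjusted p = 1.38e-06), and Aadac, a deacetylase of the liver, from 0.122 ± 0.0415 to 4.92 ± 0.595 CPM (40.4-fold, adjusted p = 1.6e-06). The transcription factor gene Irf4 fell from 2.88 ± 0.327 to 0.385 ± 0.0959 CPM (7.33-fold, adjusted p = 9.39e-06), and the neuropeptide Y receptor gene Npy1r from 14.8 ± 0.549 to 2.73 ± 0.279 CPM (5.48-fold, adjusted p = 1.3e-06). Dlk1, an imprinted gene of the Notch ligand family, fell from 169 ± 23.9 to 40.2 ± 4.74 CPM (4.28-fold, adjusted p = 5.63e-06), and Col2a1 from 27.4 ± 3.05 to 5.62 ± 0.142 CPM (4.97-fold, adjusted p = 1.74e-06).

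Of 49 fibroblast and mesenchymal genes at D4, 42 fell and 0 rose (45 changed over the list alone, median -0.50, adjusted p = 4.91e-10, and 0.452 with an estimated correlation). Osr1, a transcription factor of mesenchyme, fell from 75.5 ± 2.04 to 35.9 ± 1.95 CPM. Of 26 epithelial genes 13 rose and 3 fell (18 over the list alone, median 0.83, adjusted p = 0.000665, and 0.17 with an estimated correlation). The desmosome gene Dsp rose from 36.2 ± 1.48 to 132 ± 9.53 CPM (3.58-fold, adjusted p = 1.15e-06), while Krt19 fell from 66.3 ± 1.70 to 51.1 ± 2.71 CPM. Of 12 keratinocyte genes 6 rose and 0 fell (6 over the list alone, adjusted p = 0.00073, and 0.452 with an estimated correlation). Of 22 imprinted genes 2 rose and 16 fell (18 over the list alone, median -0.57, adjusted p = 2.1e-06, and 0.17 with an estimated correlation), Mest from 336 ± 5.07 to 166 ± 5.90 CPM. Of 39 interferon response genes 25 fell and 0 rose (26 over the list alone, median -0.41, adjusted p = 0.000119, and 0.664 with an estimated correlation), Stat2 from 369 ± 6.87 to 213 ± 8.60 CPM. Of 21 immune cell genes 16 rose and 0 fell (16 over the list alone, median 0.62, adjusted p = 2.1e-06, and 0.17 with an estimated correlation), Adgre1 from 11.7 ± 0.476 to 23.2 ± 0.764 CPM. Whether the depleted cultures at D4 held a higher share of macrophages was not tested.

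Of 25 p53 and senescence genes at D4, 14 rose and 2 fell (17 over the list alone, adjusted p = 0.0075, and 0.589 with an estimated correlation), with Ccng1 going from 385 ± 19.1 to 1155 ± 127 CPM and Mdm2, the inhibitor of p53, from 244 ± 6.60 to 434 ± 3.65 CPM. Of 23 cholesterol biosynthesis genes 12 rose and 2 fell (17 over the list alone, adjusted p = 0.0347, and 0.589 with an estimated correlation), a call lost without shCtrl replicate 3 (0.0561). Of 15 heat shock genes 10 rose and 1 fell (11 over the list alone, adjusted p = 0.0374, and 0.66 with an estimated correlation), lost without shCtrl replicate 2 (0.0976) or 3 (0.0514). Pluripotency genes did not pass at D4 (11 of 24 higher and 5 lower, 16 over the list alone, adjusted p = 0.364). In all 9 of 25 lists passed. The test called 9051 of 17001 genes, 4622 higher and 4429 lower, with 793 and 661 of them changed at least 2-fold, and the groups did not overlap in 60.3% of genes, where chance gives 10%. With library sizes alone 60.1% of called genes were higher instead of 51.1%, with a median log2 fold change of all genes of 0.07.

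Depletion at D7 asked the same of a later stage. Krt6a rose from 6.54 ± 2.27 to 208 ± 9.07 CPM (30.5-fold, adjusted p = 1.05e-06, n = 3 in each group), and Mmp10, a stromelysin, from 0.193 ± 0.135 to 14 ± 2.01 CPM (60.9-fold, adjusted p = 1.68e-06). The organic anion transporter gene Slco1a5 rose from 0.559 ± 0.282 to 25.6 ± 3.27 CPM (40.7-fold, adjusted p = 1.33e-06). Fmo2, a flavin monooxygenase, fell from 75.6 ± 5.95 to 5.77 ± 0.542 CPM (13.46-fold, adjusted p = 5.36e-07), and the GABA receptor subunit gene Gabra3 from 24.6 ± 1.27 to 1.65 ± 0.154 CPM (15.3-fold, adjusted p = 8.74e-07). Npy1r fell from 36.1 ± 1.56 to 2.72 ± 0.431 CPM (13.7-fold, adjusted p = 8.74e-07), and Nxph1 fell 33.5-fold from 1.96 ± 0.224 CPM.

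Of 36 pluripotency genes at D7, 28 rose and 1 fell (32 over the list alone, median 1.78, adjusted p = 1.02e-09, and 0.275 with an estimated correlation). Gdf3, a TGF-beta family ligand of pluripotent cells, rose from 3.50 ± 0.651 to 20.1 ± 1.76 CPM (5.54-fold, adjusted p = 2.48e-06), and the Nodal inhibitor gene Lefty2 from 0.830 ± 0.124 to 14.03 ± 3.21 CPM, while its relative Lefty1 fell from 12.01 ± 1.46 to 9.18 ± 0.231 CPM. Of 28 epithelial genes 26 rose and 0 fell (26 over the list alone, median 1.92, adjusted p = 5.13e-23, and 0.275 with an estimated correlation). Dsp went from 61.5 ± 4.63 to 220 ± 6.73 CPM and Rab25, a vesicle transport gene of epithelia, from 1.94 ± 0.245 to 14.04 ± 0.422 CPM. Of 49 fibroblast and mesenchymal genes 1 rose and 44 fell (45 over the list alone, median -0.89, adjusted p = 1.03e-14, and 0.275 with an estimated correlation), with Fbln1, a matrix protein, at 367 ± 14.6 and 123.5 ± 15.6 CPM. Of 35 cell cycle genes 29 rose and 0 fell (29 over the list alone, median 0.56, adjusted p = 9.75e-08, and 0.328 with an estimated correlation), the cyclin gene Ccnb1 from 31.2 ± 5.32 to 80.4 ± 5.21 CPM. Of 22 imprinted genes 1 rose and 17 fell (18 over the list alone, adjusted p = 3.4e-08, and 0.202 with an estimated correlation), Dlk1 from 214 ± 31.7 to 23.9 ± 6.58 CPM. Keratinocyte genes (9 of 12 higher, 1 lower, 10 over the list alone, adjusted p = 4.33e-07, and 0.275 with an estimated correlation) and muscle genes (5 of 11 higher, 0 lower, 5 over the list alone, median 0.41, mean 1.01, adjusted p = 0.000303, and 0.275 with an estimated correlation) also passed.

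TGF-beta targets at D7, with 4 of 20 higher and 12 lower (16 over the list alone), passed with an adjusted p = 0.0412 (0.307 with an estimated correlation), lost without shCtrl replicate 1 (0.0501) or shUbc9 replicate 1 (0.104). Heat shock genes, with 10 of 15 higher and 1 lower (11 over the list alone), passed with an adjusted p = 0.0347 (0.275 with an estimated correlation), lost without shCtrl replicate 1 (0.0501) or shUbc9 replicate 2 (0.0537). Germline genes, with 9 of 16 higher and 2 lower (12 over the list alone), passed with an adjusted p = 0.0217 (0.275 with an estimated correlation), and the call was lost without any of shCtrl replicates 1 (0.0542) and 3 (0.0891) and shUbc9 replicates 1 (0.104, median -0.01), 2 (0.0544) and 3 (0.0636). In all 10 of 25 lists passed. The test called 9223 of 17207 genes, 4695 higher and 4528 lower, with 1520 and 1092 changed at least 2-fold, and the groups did not overlap in 58.2% of genes, where chance gives 10%. With library sizes alone 71.5% of called genes were higher instead of 50.9%, with a median log2 fold change of all genes of 0.21.

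**Figure D1:**
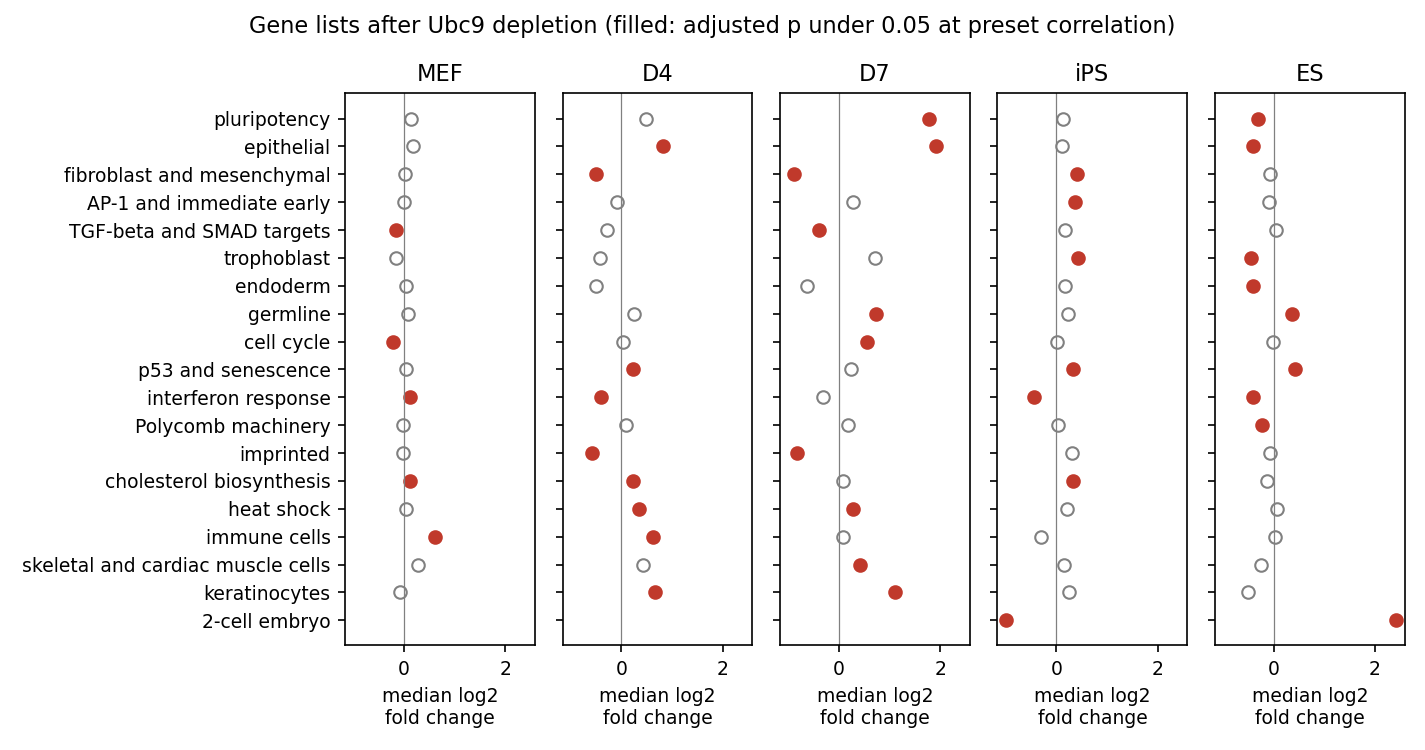
Median log2 fold change after Ubc9 depletion (horizontal axis) of each gene list that passed in at least 1 state (vertical axis), in 5 panels by cell state; filled points passed camera at the preset correlation. Epithelial genes lay at 1.92 at D7 and at -0.40 in ES cells, and 2-cell embryo genes at 2.42 in ES cells.

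To ask whether depleted cultures lay nearer to the ES controls, all genes that separate MEF from ES controls were taken as sets. Of 3507 somatic genes tested at D4, 46.6% fell and 17.2% rose (median log2 fold change -0.25, adjusted p = 1.57e-09, and 0.00119 with an estimated correlation). Of 2331 pluripotent genes, 35.6% rose and 12.3% fell (median 0.18, adjusted p = 8.57e-06, and 0.0202 with an estimated correlation). At D7, 53% of 3486 somatic genes fell and 11.5% rose (median -0.38, adjusted p = 6.51e-18, and 0.000222 with an estimated correlation), and 54.1% of 2484 pluripotent genes rose and 6.24% fell (median 0.56, adjusted p = 6.51e-18, and 0.00929 with an estimated correlation). Among genes of neither set, 28.6% rose and 22.5% fell at D4, and 26.3% and 22.5% at D7.

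On the axis from MEF shCtrl (0%) to ES siCtrl (100%), drawn from 7363 somatic and pluripotent genes, D4 cells lay at 10.6 ± 0.706% in controls and 16.4 ± 0.681% after depletion (n = 3 each), a difference of 5.74 points. D7 cells lay at 12.6 ± 0.720% and 23.8 ± 1.19%, a difference of 11.2 points. The exact two-sided permutation test gave p = 0.1 at each stage, the smallest value that 3 against 3 can give. From somatic genes alone, D7 cells lay at 3.82% and 12.9%, and from pluripotent genes alone at 21.4% and 34.6%. MEF shUbc9 lay at 0.453 ± 0.204% (n = 2), ES siUbc9 at 96.9 ± 0.180% (n = 3), iPS shCtrl at 73.7 ± 3.71% (n = 2) and iPS shUbc9 at 72.5 ± 4.43% (n = 3). Pou5f1, whose counts may include the cassette, was at 33.5 ± 1.76 CPM in D7 shCtrl and 89.4 ± 14.4 CPM in D7 shUbc9. Whether the level of the reprogramming factors moved cells along the axis was not tested. Each library gives 1 position for a whole culture. A part-way move of all cells could therefore not be told from a longer move of some of them.

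**Figure D2:**
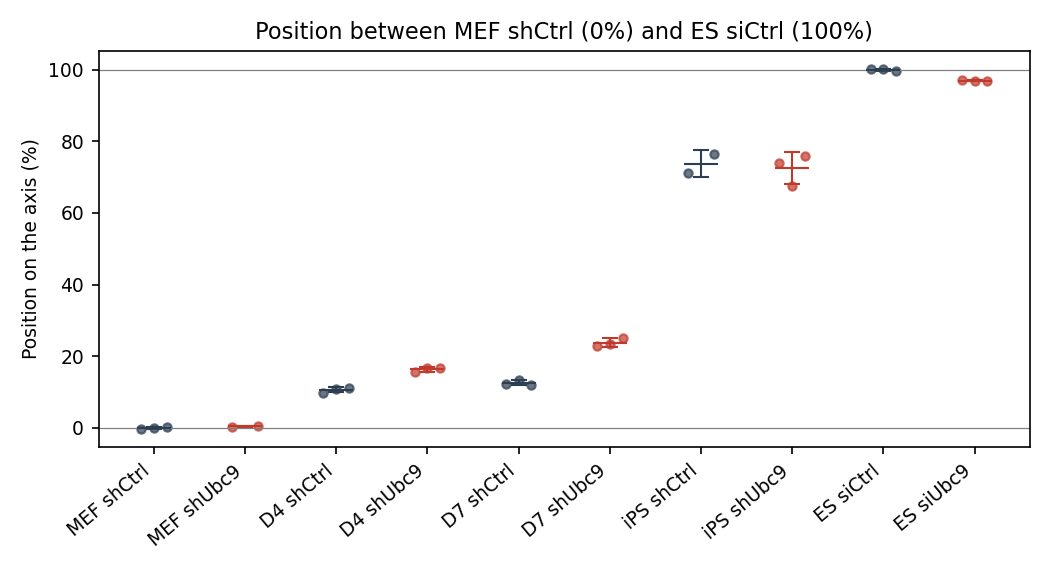
Position of each RNA library between MEF shCtrl (0%) and ES siCtrl (100%), in percent on the vertical axis, by group on the horizontal axis (points, libraries; bars, mean and SD; red, Ubc9 depleted). D7 shUbc9 libraries lay at 22.8% to 25.1%, above the D7 controls at 12.1% to 13.4%.

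In ES cells depletion tested what SUMO does in the pluripotent state. Serpina3m, a serine protease inhibitor, rose from 0.414 ± 0.0892 to 28.9 ± 0.884 CPM (71.7-fold, adjusted p = 8.95e-09, n = 3 in each group), and Mmp12, the macrophage elastase, from 0.0819 ± 0.0362 to 7.90 ± 0.610 CPM (96.2-fold, adjusted p = 7.01e-08). Csta2, a stefin that inhibits cysteine proteases, rose from 0.0401 ± 0.0181 to 10.4 ± 0.972 CPM (248-fold, adjusted p = 3.29e-08), and the zinc transporter gene Slc39a12 was at 0 in controls and at 6.83 ± 0.731 CPM after depletion, at least 335-fold higher. The homeodomain gene Hopx fell from 11.5 ± 0.574 to 2.49 ± 0.0158 CPM (4.49-fold, adjusted p = 1.99e-07), and Krt17 from 14.7 ± 1.83 to 3.62 ± 0.114 CPM (3.93-fold, adjusted p = 1.04e-06).

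Genes of the 2-cell embryo rose together in ES cells: 30 of 34 were higher and 3 lower (34 over the list alone), with a median log2 fold change of 2.42 and an adjusted p = 8.23e-86, and 0.00816 with an estimated correlation. It was the one list of any state whose call held with the estimated correlation. Zscan4c and Zscan4d, markers of ES cells that resemble 2-cell embryos, rose from 15.8 ± 1.16 to 141 ± 5.71 CPM (9.21-fold, adjusted p = 8.95e-09) and from 17.3 ± 1.05 to 160 ± 7.33 CPM (9.56-fold, adjusted p = 8.95e-09). Pramel7, by contrast, fell from 2.12 ± 0.0913 to 1.17 ± 0.109 CPM. Of 37 pluripotency genes 21 fell and 4 rose (26 over the list alone, median -0.30, adjusted p = 5.45e-05, and 0.419 with an estimated correlation). Nanog fell from 99.9 ± 3.79 to 49.8 ± 2.87 CPM and Fgf4 from 257 ± 19.4 to 132 ± 1.91 CPM, while Dppa3, which is also a germline gene, rose from 5.54 ± 1.06 to 25.9 ± 0.392 CPM.

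Of 28 epithelial genes in ES cells 16 fell and 1 rose (17 over the list alone, median -0.40, adjusted p = 0.000183, and 0.22 with an estimated correlation), with Dsp falling from 43.5 ± 3.19 to 18.0 ± 0.725 CPM and Epcam rising from 164 ± 12.5 to 284 ± 22.6 CPM. Of 23 p53 and senescence genes 16 rose and 2 fell (18 over the list alone, adjusted p = 4.21e-06, and 0.113 with an estimated correlation), the apoptosis gene Pmaip1 from 35.5 ± 4.80 to 111 ± 4.31 CPM. Of 35 germline genes 20 rose and 4 fell (24 over the list alone, adjusted p = 0.00148, and 0.383 with an estimated correlation), Dazl from 31.5 ± 4.05 to 93.5 ± 3.25 CPM. Interferon response genes (3 of 32 higher, 18 lower, 22 over the list alone, adjusted p = 0.00116, and 0.22 with an estimated correlation) included Irf1, which fell from 117 ± 0.893 to 50.6 ± 1.38 CPM. Endoderm genes (0 of 18 higher, 11 lower, 14 over the list alone, adjusted p = 0.00402, and 0.419 with an estimated correlation), trophoblast genes (0 of 14 higher, 6 lower, 6 over the list alone, adjusted p = 0.0116, and 0.263 with an estimated correlation) and Polycomb genes (3 of 26 higher, 17 lower, 21 over the list alone, adjusted p = 0.00628, and 0.344 with an estimated correlation) were the other lists that passed, 9 of 27 in all. The test called 6986 of 17859 genes, 3809 higher and 3177 lower, with 1303 and 384 changed at least 2-fold, and the groups did not overlap in 51.4% of genes, where chance gives 10%.

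In iPS cells the edgeR test called 0 of 17294 genes after shUbc9 (n = 2 controls and 3 depleted), where 246 had an unadjusted p under 0.05 and DESeq2 called 10. The simulated data showed that even 4-fold changes could not be called in this design, whose biological coefficient of variation was 0.442, against 0.0747 in ES cells. The Y-linked gene Eif2s3y was at 83.6 ± 1.17 CPM in shCtrl and at 0.342 ± 0.292 CPM in shUbc9, and shUbc9 replicate 2 had the fewest counts of all libraries (11.4 M). Camera called 7 of 26 lists, with 0 changed members in each. The 2-cell embryo list had a median of -0.99 (adjusted p = 1.44e-07, and 0.51 with an estimated correlation), which became 0.21 (adjusted p = 0.722) without shCtrl replicate 1. The interferon list had a median of -0.43 (adjusted p = 2.74e-05, and 0.605 with an estimated correlation), which became 0.19 (0.866) without shCtrl replicate 1 and -0.23 (0.282) without shUbc9 replicate 3. The fibroblast list (median 0.41, adjusted p = 0.0043, and 0.605 with an estimated correlation) lost its call without shCtrl replicate 3 (0.52) or shUbc9 replicate 2 (0.971). AP-1 genes (median 0.36, adjusted p = 0.00127), cholesterol biosynthesis genes (0.34, 0.0017), trophoblast genes (0.42, 0.00798) and p53 genes (0.33, 0.0181) had an adjusted p = 0.461 with an estimated correlation, and each call was lost without single libraries. These were shCtrl replicate 1 (adjusted p = 0.0826) and shUbc9 replicate 2 (0.111) for AP-1 genes, shCtrl replicate 1 (0.0826) and shUbc9 replicate 3 (0.0888) for cholesterol biosynthesis genes, and shCtrl replicate 3 (0.148) and shUbc9 replicate 3 (0.0888) for trophoblast genes. For p53 genes they were shCtrl replicate 1 (0.16), shUbc9 replicate 2 (0.0589) and shUbc9 replicate 3 (0.205). Without shUbc9 replicate 1, 12 lists passed, and without shUbc9 replicate 3, 4 did. Somatic genes had a median of 0.13 (adjusted p = 0.00388, and 0.558 with an estimated correlation), which became -0.04 without shCtrl replicate 3 (adjusted p = 0.318) and 0.008 without shUbc9 replicate 2 (0.733). Pluripotent genes had a median of -0.03 (adjusted p = 0.288), which became 0.02 without shCtrl replicate 3 (adjusted p = 0.943).

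Transcripts of endogenous retroviruses rose in ES cells after depletion. IAPEz-int, the internal part of the intracisternal A particle, rose from 508 ± 32.3 to 4535 ± 221 CPM (9.22-fold, adjusted p = 2.45e-12, n = 3 each), and MMERVK10C-int from 578 ± 16.7 to 2829 ± 124 CPM (5.05-fold, adjusted p = 1.54e-10). MERVL-int, which is transcribed in the 2-cell embryo, rose from 1125 ± 48.2 to 3684 ± 187 CPM (3.38-fold, adjusted p = 6.08e-09), and L1Md_T, a LINE-1 family, 1.53-fold (adjusted p = 0.00156). Of 770 families 57 rose and 3 fell, and of 358 long terminal repeat families 44 rose and 1 fell. At D7, 11 of 767 families rose and 23 fell: MMETn-int rose from 153 ± 2.96 to 500 ± 28.2 CPM (3.19-fold, adjusted p = 1.78e-08) and IAPEz-int from 381 ± 24.4 to 758 ± 94.6 CPM (1.94-fold, adjusted p = 0.000358), while MTEb-int fell from 113 ± 12.6 to 56.3 ± 0.958 CPM. At D4, 2 of 769 families rose, MER34B-int among them (adjusted p = 0.0348), and MLT1H-int fell from 58.2 ± 0.694 to 33.2 ± 2.56 CPM (adjusted p = 0.0073). No family passed in MEF (0 of 752) or iPS (0 of 762) in edgeR, where 35 and 2 families had an unadjusted p under 0.05.

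The median log2 fold change of all families was -0.19 in MEF, -0.30 at D4, -0.22 at D7, -0.58 in iPS and -0.07 in ES cells, relative to genes, and scaling by repeat families alone called 55 families at D4 (37 higher and 18 lower), 75 at D7 (50 higher and 25 lower, so that most rose instead of fell) and 267 in ES cells (169 higher and 98 lower), with IAPEz-int and MERVL-int still higher in ES cells. The medians and counts of families moved with single libraries. With each library left out, the median ranged from -0.30 (without shCtrl replicate 2) to -0.12 (without shUbc9 replicate 3) in MEF, from -0.43 (without shUbc9 replicate 2) to -0.18 (without shUbc9 replicate 3) at D4, and from -0.33 (without shCtrl replicate 2) to -0.08 (without shCtrl replicate 3) at D7. It ranged from -0.83 (without shCtrl replicate 3) to -0.29 (without shUbc9 replicate 2) in iPS, where it was -0.31 without shCtrl replicate 1. In ES cells it was -0.15, 0.04 and -0.10 without siCtrl replicates 1, 2 and 3, and 0.009, -0.12 and -0.11 without siUbc9 replicates 1, 2 and 3, so its sign turned. In MEF 473 passed without shCtrl replicate 2. At D4 389 passed without shUbc9 replicate 2, 5 without shCtrl replicate 2, and 0 without shCtrl replicate 1 or shUbc9 replicate 1. At D7 365 passed without shCtrl replicate 2, 58 without shCtrl replicate 3, 13 without shCtrl replicate 1, and 15, 15 and 12 without shUbc9 replicates 1, 2 and 3.

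**Figure D3:**
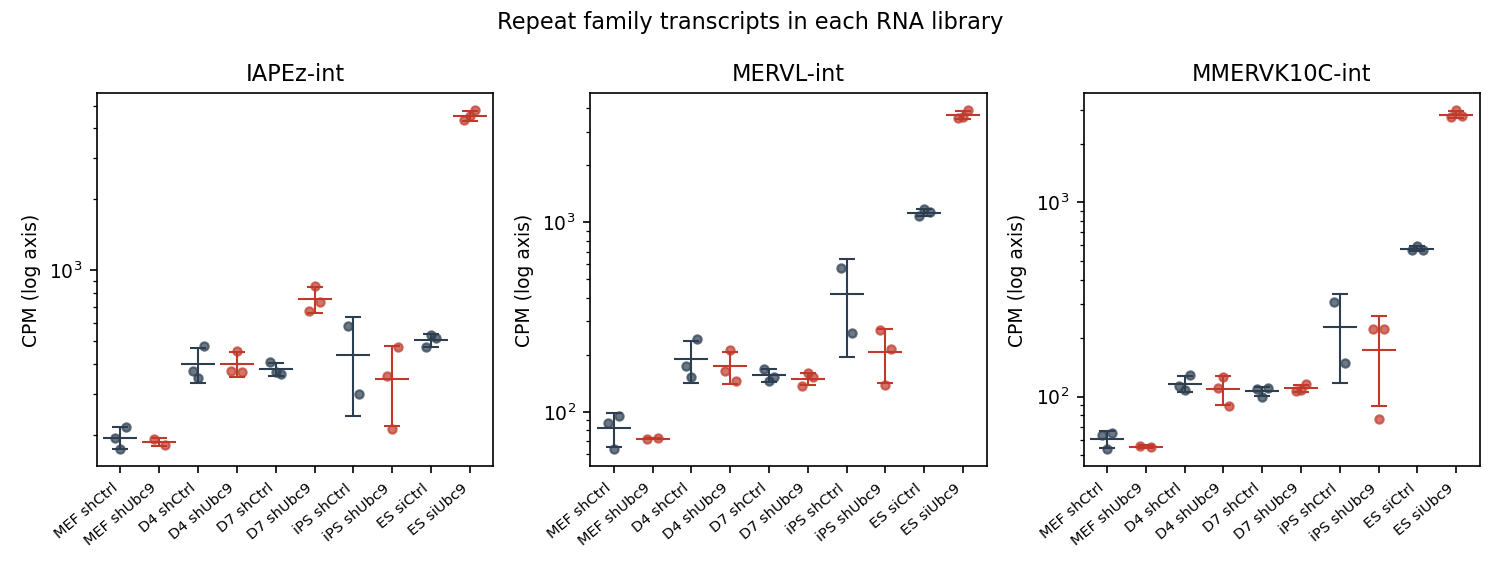
Transcript level of repeat families in each RNA library, in CPM on a log axis (vertical), by group (horizontal); points, libraries, bars, mean and SD, red, Ubc9 depleted. IAPEz-int reached 4535 CPM in ES siUbc9, against 508 CPM in ES siCtrl.

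Some lists that did not pass had a median, mean and test that differed in sign. These were endoderm genes in MEF, SUMO pathway genes at D4, at D7 and in ES cells, AP-1 genes at D4 and in ES cells, trophoblast and neuroectoderm genes at D4, Polycomb genes at D4 and in iPS, and neural crest genes at D7, in iPS and in ES cells. The others were immune and cell cycle genes in iPS, mesoderm genes in iPS and ES cells, and TGF-beta target, endothelial and erythroid genes in ES cells. SUMO pathway genes had a median of 0.07 and a mean of -0.03 at D4, with 7 of 22 higher and 4 lower (11 over the list alone, adjusted p = 0.843). In ES cells 2 rose and 5 fell (6 over the list alone, adjusted p = 0.172). Erythroid genes had 1 of 5 higher and 1 lower in ES cells (2 over the list alone, adjusted p = 0.937).

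Genes changed at D4 and at D7 overlapped most: 3075 rose and 3157 fell at both stages, where 1220 and 1180 would be shared if the calls were independent. Between D7 and ES cells, 848 genes rose in both, 773 fell in both, 983 rose at D7 and fell in ES cells and 935 fell at D7 and rose in ES cells, where 854 and 755 would be shared in the same direction. The iPS comparison called 0 genes, so at least 4 of the 5 states could only mean MEF, D4, D7 and ES cells. In all 4 of these, 56 genes rose and 36 fell. Those with the largest mean change were the proteases Mmp10, Mmp12 and Mmp3, Akr1c18, Slpi, Tnfrsf26 and Slfn4, which rose, and Kcnj8, Ptchd1 and Meox1, which fell. Mmp10 had log2 fold changes of 3.02 in MEF, 3.74 at D4, 5.93 at D7 and 3.74 in ES cells, and Meox1, a mesodermal homeobox gene, of -0.51, -1.86, -1.87 and -1.54.

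Whether the response differed between states was tested directly. It differed between ES and MEF for 3975 of 19333 genes, of which 1984 were shifted up and 1991 down in ES cells, between D7 and D4 for 2171 of 17676 genes (1068 up and 1103 down at D7), and between iPS and ES for 262 of 19186 genes (62 up and 200 down in iPS). Csta2 differed by 6.93 on the log2 scale between ES and MEF, and Reg1 by -2.80 between D7 and D4. The count for D7 and D4 was 1386 without D7 shCtrl replicate 1, and with library sizes alone 72.9% of its genes were shifted up instead of 49.2%. The count for iPS and ES was 1518 without iPS shUbc9 replicate 2 (847 up and 671 down, so that the majority direction turned) and 136 without iPS shCtrl replicate 1. It was 84, 83 and 83 without ES siCtrl replicates 1, 2 and 3, and 99, 78 and 74 without ES siUbc9 replicates 1, 2 and 3.

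The peak lists have 1 merged list per antibody and condition, so no replicate error is given for them. SUMO-1 had 12408 peaks in MEF and 12339 in ES cells, and SUMO-2 had 9979 and 12014. Of SUMO-1 peaks in MEF, 9.16% (95% Wilson interval 8.66 to 9.68%) overlapped one in ES cells, where 100 circular shifts gave at most 0.846%. In MEF, 60.2% of SUMO-2 peaks lay on H3K27ac, the acetylation of active enhancers and promoters, 50.1% on H3K4me1, 9.48% on H3K9me3, 6.22% on H3K4me3 and 0.321% on H3K27me3, and 48.4% of SUMO-1 peaks lay on H3K27ac (at most 3.51% by chance for SUMO-2 and 5.44% for SUMO-1). In ES cells, 24.7% (24.0 to 25.5%) of SUMO-1 peaks lay on H3K9me3, the mark of heterochromatin (at most 0.770% by chance), 14.2% on H3K27ac and 10.1% on H3K4me3. SUMO-1 peaks found in both cell types overlapped H3K9me3 of MEF in 29.9% of cases (27.3 to 32.7%), against 4.77% (4.39 to 5.18%) of those only in MEF. In ES cells the shares on H3K9me3 were 23.0% (20.6 to 25.5%) and 24.9% (24.1 to 25.7%), so this difference was not found there. The SUMO-1 peak with the highest authors' score in MEF was on chromosome 13 at 64270820 to 64271533 (mm9, score 6712), and the highest in ES cells on chromosome 13 at 64270319 to 64272057 (score 6372), both on H3K9me3.

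At D4 the peaks of histone marks were compared with those that only MEF or only ES cells have. Of 24952 H3K27ac peaks found in MEF and not in ES cells, 37.3% (36.7 to 37.9%) were found at D4 in shCtrl and 33.5% (32.9 to 34.1%) in shUbc9. Of 13635 H3K27ac peaks found in ES cells and not in MEF, 10.3% (9.82 to 10.8%) and 12.7% (12.1 to 13.2%) were found. For H3K4me3, the mark of promoters, 16.2% of ES-only peaks were found in shCtrl and 24.1% in shUbc9, and 77.1% and 83.6% of MEF-only peaks, with 16322 and 18698 peaks in the lists. For H3K4me1 the shares of MEF-only peaks were 20.1% and 18.1% and of ES-only peaks 4.87% and 7.55%. For H3K27me3, the Polycomb mark, they were 36.1% and 33.0%, and 22.6% and 20.2%. For H3K9me3 they were 13.4% and 14.6%, and 6.59% and 8.91%.

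**Figure D4:**
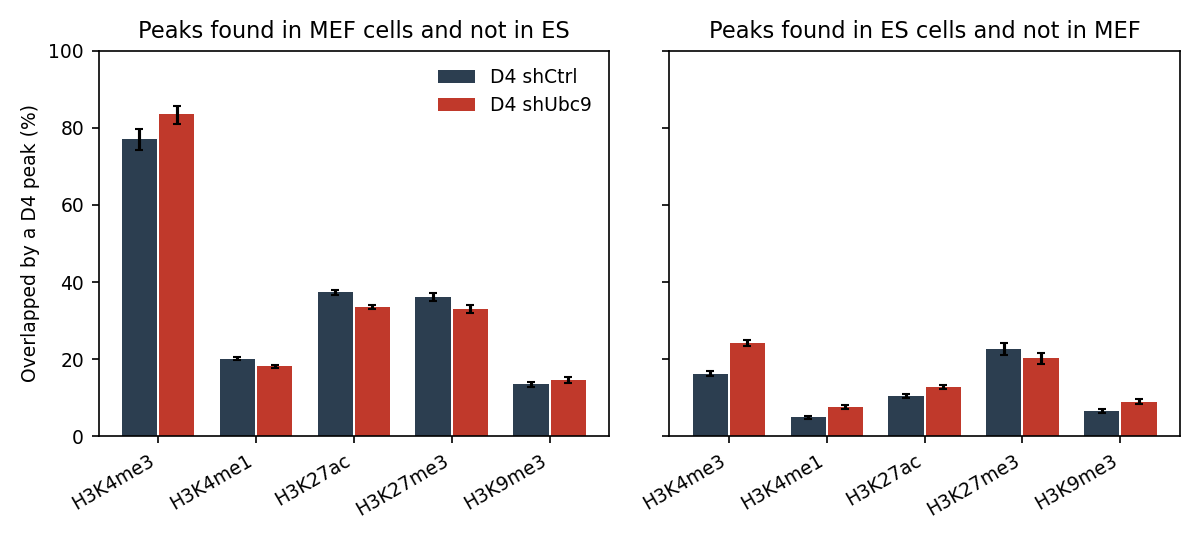
Share of cell-type-specific peaks of each histone mark (horizontal axis) that a D4 peak overlaps, in percent (vertical axis), for MEF-only peaks (left) and ES-only peaks (right); bars, D4 shCtrl and D4 shUbc9, error bars, 95% Wilson intervals. For H3K4me3, 24.1% of ES-only peaks were found in shUbc9 and 16.2% in shCtrl.

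Peaks of the reprogramming factors at D4 were more numerous after depletion: Oct4 had 16740 in shCtrl and 23477 in shUbc9, Sox2 had 20197 and 27514, and Klf4 had 34163 and 37505. Transcripts of Pou5f1, which encodes Oct4, were at 30.8 ± 5.62 CPM in D4 shCtrl and 49.8 ± 7.07 CPM in D4 shUbc9, without overlap. Sox2 was at 24.6 ± 4.79 and 30.5 ± 5.20 CPM and Klf4 at 107 ± 12.9 and 95.1 ± 7.55 CPM, with overlap. Whether factor levels account for the added peaks was not tested. Of shUbc9 peaks, 59.2% (58.6 to 59.9%) of Oct4, 65.9% (65.4 to 66.5%) of Sox2 and 79.7% (79.3 to 80.1%) of Klf4 were shared with shCtrl. In the other direction, 83.4% of Oct4, 90.3% of Sox2 and 88.0% of Klf4 peaks of shCtrl were shared with shUbc9. Most control peaks were thus found after depletion too, and the lower shares belong to the longer shUbc9 lists. Oct4 peaks only in shCtrl lay on MEF-only H3K27ac peaks in 31.0% of cases, and those only in shUbc9 in 14.2%, which were 862 of 2779 and 1357 of 9571 peaks. On ES-only H3K27ac peaks these shares were 5.33% and 11.3%. Of Sox2 peaks, 32.1% of those only in shCtrl and 14.9% of those only in shUbc9 lay on MEF-only H3K27ac, and of Klf4 peaks 28.4% and 7.81%. In number, MEF-only H3K27ac held 4027 Oct4 peaks in shCtrl and 4544 in shUbc9, 5082 and 5828 Sox2 peaks, and 7644 and 7048 Klf4 peaks, so for Oct4 and Sox2 the lower share came with more peaks. MEF SUMO peaks were overlapped by 21.0% of Oct4 peaks only in shCtrl (584 peaks) and by 7.54% of those only in shUbc9 (722 peaks).

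In ES cells H3K9me3 had 21492 peaks over 31.0 Mb in siCtrl and 18745 peaks over 21.1 Mb in siUbc9, 68.2% of the length. The other H3K9me3 list of ES cells, labelled without siCtrl or siUbc9 and used for the SUMO overlaps above, held 8508 peaks over 9.35 Mb. Lists of ES cells without depletion thus differed more in size than siCtrl and siUbc9 did. With 1 merged list per condition, a loss of the mark could not be told from a difference between lists. Of siCtrl peaks, 55.9% (55.2 to 56.6%) overlapped a siUbc9 peak. Among siCtrl peaks with a SUMO peak of ES cells, 47.3% (45.6 to 48.9%) were kept, against 57.7% (56.9 to 58.4%) of those without, an odds ratio of 0.659 (two-sided Fisher's exact test over peaks, p = 4.57e-30, peaks not being replicates). Within 4 parts of the authors' score range the odds ratio was 0.475, 0.580, 0.563 and 0.321. A SUMO peak lay on 20.0% of peaks only in siCtrl and on 7.14% of those only in siUbc9.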

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

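The tests of the source of pluripotency transcripts in MEF shUbc9 replicate 3 and of Y-linked transcripts in iPS shUbc9 were chosen after the results were seen, and the label permutations for D7 and D4 before.

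The response to Ubc9 depletion differed between ES cells and MEF for 3975 genes in a test of the difference itself. Relative to MEF, the response in ES cells was higher on the log2 scale by 10.38 for Slc39a12, 6.93 for Csta2, 6.30 for Mmp1b, 6.17 for Mndal and 5.92 for Csta1, of which Csta2 and Csta1 are inhibitors of cysteine proteases. Slc39a12 was at 0 in ES siCtrl, so its fitted value depends on the prior count and is no measured difference. It was lower, with differences of -7.86 for Fgf4, -6.63 for Lin28a, -5.88 for Sall4 and -5.30 for Dppa2. The call for Csta1 was lost without MEF shCtrl replicate 1 and in the fit of all RNA libraries with a shared spread, and the range of its log2 value over all alternatives was 4.996 to 8.351.

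These 4 lower genes were at 0 in MEF shCtrl, so that their fitted values depend on the prior count too, and in MEF shUbc9 their counts came from replicate 3, so that Fgf4 was at 0.338 ± 0.478 CPM and Lin28a at 0.242 ± 0.342 CPM (SD, n = 2). Of 21 genes high in iPS shCtrl and near 0 in control MEF, replicate 3 had counts for 18, 126 in sum, and replicate 1 had 4 counts, or 3.23% of its level, which argues against an effect of depletion in fibroblasts. Over 44 genes high in iPS or ES cells the counts in replicate 3 lay closer to the iPS shCtrl profile (Poisson deviance 69.8) than to that of ES siCtrl (134), and over the 21 genes they were at 0.107% of the iPS level. RNA or reads of iPS cells in that library are a candidate explanation. Without that library the log2 value of Dppa2 became 0.02, and no fall of pluripotency genes in ES relative to MEF was read from these 4 genes.

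Between D7 and D4 the response differed for 2171 genes. It was higher at D7 by 4.06 for the protease gene Klk6, 4.05 for Clec2i, 3.74 for Cyp2b23, 3.47 for the lipoxygenase gene Alox15 and 3.35 for H2ac12. It was lower for 5 others, with -2.80 for Reg1, -2.48 for Ear2, -2.30 for Glyat, -2.28 for Clca3a2 and -2.15 for Serpina3c. Of 100 label permutations within the stages, of 200 possible, 8 gave as many genes, the real one included, with 6900 the highest other count. All 7 others kept 1 stage as labelled and with it the effect of depletion at that stage, so this test does not decide whether chance gives as many genes, and the highest count with both stages broken up was 0. The calls for Klk6, Clec2i, Cyp2b23 and Alox15 were each lost without D4 shCtrl replicate 2, and that for Klk6 also without D4 shCtrl replicate 1, D4 shUbc9 replicate 1 or D4 shUbc9 replicate 2. The largest adjusted p over the alternatives was 0.126 for Klk6, 0.132 for Clec2i, 0.300 for Cyp2b23 and 0.214 for Alox15. The call for Cyp2b23 was lost without D4 shCtrl replicate 3 as well, and those for Clec2i, Cyp2b23 and Alox15 in the fit of all RNA libraries with a shared spread.

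Between iPS and ES cells the response differed for 262 genes. It was higher in iPS by 4.32 for Bcl2l15, 3.89 for the transcription factor Gata3, 3.003 for Ccno, 2.74 for Fam167a and 2.68 for Krt17. Lower responses were -11.07 for Uba1y, -8.52 for Kdm5d, -8.48 for Csta2, -8.35 for Zfy1 and -8.11 for Eif2s3y. The calls for Bcl2l15 and Gata3 were lost without any 1 of the 6 ES libraries, either iPS shCtrl library or iPS shUbc9 replicate 3, with a largest adjusted p of 0.118 and 0.128. The call for Csta2 was lost without iPS shCtrl replicate 1 (largest adjusted p 0.0923) and that for Fam167a without ES siUbc9 replicate 3 (0.0536).

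Uba1y, Kdm5d, Zfy1 and Eif2s3y lie on the Y chromosome, and the median log2 change of 6 Y-linked genes in iPS was -7.67. In MEF, D4, D7 and ES cells the lowest median of the Y-linked genes was -0.018, in MEF, which argues against a fall of these genes as a set with depletion. Single members did change. In ES cells Kdm5d rose from 2.94 to 5.92 CPM and Uba1y from 32.5 to 68.8 CPM, while at D4 Kdm5d went from 25.5 to 21.2 CPM. The values of Uba1y and Kdm5d for iPS against ES cells include these rises in ES cells. In the 3 iPS shUbc9 libraries the highest share of the iPS shCtrl mean kept by a Y-linked gene was 3.29%. Lines without a Y chromosome are a candidate explanation, and the genetic source of the iPS lines then stays open as a difference between shCtrl and shUbc9.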

How the results depend on the processing

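Scaling by library size alone, other scalings of repeat families, each library left out for repeat families, and leaving out both shallow libraries together were tests chosen after seeing the data. The alternatives that place SUMO peaks within 5 kb or 1 kb of a gene start were not run, as no gene coordinates on mm9 were used. Of 427 named gene results, 304 kept direction and call under every alternative run, as did 10 of 41 results that answer a comparison and 1 of 40 single lists and other values. With each library left out in turn, 2553 named gene values were kept, 113 lost their call and 1 reversed. Under other alternatives 2413 were kept. The fit of all RNA libraries with a shared spread ended 110 calls, library size alone 6, a replicate block 6 and no filter 1. DESeq2 and its size factors ended 0 of the named calls. The causes of the changes below were not tested, except that leaving out libraries leaves fewer samples.

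In 1 fit of all RNA libraries with a shared spread, the genes called were 42 in MEF, 4417 at D4, 920 in iPS, 2722 in ES cells, 6252 between D4 and MEF controls, 1019 between D7 and D4 controls, 848 for the difference between ES and MEF, 405 for D7 and D4, and 1847 for iPS and ES (1120 up and 727 down). With a replicate block they were 1868 in MEF (850 higher and 1018 lower, so the majority direction turned), 81 in iPS, 4608 between D7 and D4 controls, 1019 for the difference between D7 and D4, and 495 for iPS and ES (262 up and 233 down), and the iPS medians were 0.016 for somatic genes (adjusted p = 0.945) and -0.009 for pluripotent genes (adjusted p = 0.895), where the direction of the test reversed. Deviations of libraries with the same number did not pair in MEF, D4, D7 and iPS (correlations of -0.507 to -0.021), so this paired fit stands only here. In ES cells they were 0.326, 0.235 and 0.092, against -0.31 to 0.223 for different numbers, so a weak pairing stays open there. DESeq2 called 10 genes in iPS and 862 for the difference between iPS and ES. In iPS, DESeq2 size factors gave 1 gene and no filter gave 5. Without both shallow libraries, iPS shUbc9 replicate 2 and ES siUbc9 replicate 1, 974 genes differed between iPS and ES (542 up and 432 down). The majority direction for iPS and ES turned in the fit of all RNA libraries, with the replicate block and without both shallow libraries. With DESeq2 (389 up and 473 down) it did not turn. At D4, at D7 and in the differences in response between ES and MEF and between D7 and D4, where nearly as many genes went up as down, it turned under at least 1 alternative each.

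With an estimated correlation camera called 0 lists in MEF, 0 at D4, 0 at D7, 0 in iPS and 1 in ES cells, and fry called 1 in MEF, 15 at D4, 0 in iPS and 15 in ES cells. Somatic genes in iPS, with a median of 0.132, had an adjusted p = 0.558 with an estimated correlation and 0.654 with fry. Pluripotent genes in iPS, taken from 2-fold, had a median of -0.076 (adjusted p = 0.0101). Repeat families called at D4 were 11 with genes and repeats scaled together, and with repeat families alone 55 at D4, 75 at D7 (50 higher and 25 lower, so the majority direction turned) and 267 in ES cells.

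In the upper 50% of each peak list by score, 7.88% of SUMO-1 and 8.96% of SUMO-2 peaks of MEF were shared with ES cells, MEF-only H3K27ac was found at D4 for 39.9% in shCtrl and 37.0% in shUbc9, and ES-only H3K27ac for 14.6% and 15.2%. Peaks of shUbc9 were shared with shCtrl for 55.6% of Oct4, 77.2% of Klf4 and 65.0% of Sox2. With at least 50% of a peak covered, MEF-only H3K27ac was found for 32.1% and 28.4%, ES-only H3K27ac for 11.5% in shUbc9, and 53.9% of Oct4, 75.9% of Klf4, 60.8% of Sox2 and, in ES cells, 51.2% of H3K9me3 peaks were shared. With equal numbers of the strongest peaks, 9.10% of SUMO-2 peaks, 46.9% and 42.5% of MEF-only and 16.1% and 18.2% of ES-only H3K27ac peaks, 70.3% of Oct4, 83.9% of Klf4, 78.1% of Sox2 and 61.0% of H3K9me3 peaks were shared. MEF-only H3K27ac stayed lower and ES-only H3K27ac higher in shUbc9 in each.

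With each library left out, called genes ranged from 266 to 1717 in MEF, 7281 to 8937 at D4, 6998 to 9125 at D7, 0 to 2 in iPS and 5176 to 7582 in ES cells. They ranged from 16185 to 16617 between ES and MEF controls, 10011 to 11369 between D4 and MEF, 1669 to 2955 between D7 and D4 and 6767 to 12396 between iPS and ES. The differences in response ranged from 2752 to 4156 for ES and MEF, 1386 to 2866 for D7 and D4, and 74 to 1518 for iPS and ES, and the log2 value of Dppa2 in the first from -6.29 to 0.016. Lists called ranged from 4 to 8 in MEF, 8 to 13 at D4, 7 to 10 at D7, 4 to 12 in iPS and 9 to 10 in ES cells. In iPS the medians of the fibroblast and interferon lists ranged from 0.094 to 0.579 and from -0.967 to 0.189. Signature medians ranged from -0.263 to -0.237 (somatic, D4), 0.155 to 0.200 (pluripotent, D4), -0.404 to -0.384 (somatic, D7), 0.531 to 0.571 (pluripotent, D7), -0.044 to 0.371 (somatic, iPS) and -0.081 to 0.023 (pluripotent, iPS), and the axis difference from 5.33 to 6.13 points at D4 and 10.5 to 11.7 at D7. Repeat families ranged from 0 to 473 in MEF, 0 to 389 at D4, 12 to 365 at D7, 0 to 2 in iPS and 43 to 89 in ES cells. Depth limited rare transcripts most in iPS shUbc9 replicate 2 (11.4 M) and ES siUbc9 replicate 1 (17.4 M).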

Other observations

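The tests on immune cell genes in MEF and on H3K27ac at SUMO peaks were chosen after the results were seen, and the other splits of libraries before.

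Of 22 SUMO pathway genes 7 rose and 4 fell at D4 (11 over the list alone), 5 rose and 6 fell at D7 (11), and 2 rose and 5 fell in ES cells (6). The list did not pass in these states (adjusted p = 0.843, 0.869 and 0.172, though 0.0201 and lower with fry in ES cells), and its share of changed genes was no higher than that of all genes, 9051 of 17001 at D4, 9223 of 17207 at D7 and 6986 of 17859 in ES cells. Single members changed. Sumo3 rose from 134 ± 8.32 to 205 ± 18.9 CPM at D4 (adjusted p = 0.000348) and from 134 ± 8.75 to 197 ± 7.99 CPM at D7 (adjusted p = 0.000161, n = 3 each). In ES cells the SUMO protease gene Senp6 rose from 175 ± 12.5 to 280 ± 10.4 CPM (adjusted p = 1.62e-05), and Senp3 fell from 437 ± 15.2 to 256 ± 5.05 CPM (adjusted p = 6.63e-06). Of 28 heterochromatin genes in ES cells 3 rose and 8 fell, and Atf7ip, a partner of the H3K9 methyltransferase Setdb1, rose from 155 ± 20.7 to 336 ± 11.02 CPM, while the list as a whole had an adjusted p = 0.403.

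Nes, an intermediate filament gene of neural progenitors, rose at D7 from 38.3 ± 4.46 to 165 ± 9.73 CPM (adjusted p = 1.05e-06, n = 3 each). Hprt and Nanog were chosen after their values were seen. Hprt, which is X-linked, was at 0.773 ± 0.0726 CPM in ES siCtrl, against 72.3 CPM in MEF shCtrl and 143 CPM in iPS shCtrl, and the cause was not tested. Nanog was at 1.64 ± 0.995 CPM in D7 shCtrl and 9.67 ± 1.38 CPM in D7 shUbc9.

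In MEF, 7 of 21 immune cell genes lay more than 3 SE from the median log2 change of their list, 0.61. C1qa, C1qb, C1qc, Coro1a and Cx3cr1 were below it and Itgam and Lyz1 above it, which argues against a higher share of macrophages in the shUbc9 cultures as the only explanation, while a change within macrophages stays open. The largest adjusted p of the list with each library left out was 4.16e-14 at the preset correlation, so that 1 library alone did not account for that call, which an estimated correlation ended (adjusted p = 0.46).

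H3K27ac at D4 was compared between MEF-only peaks with and without a MEF SUMO peak. Of those found at D4 in shCtrl, 24.1% (22.3 to 25.9%) with SUMO were not found in shUbc9, against 20.4% (19.5 to 21.4%) without, and the share was higher with SUMO in 4 of 4 parts of the score range. Peaks found in shUbc9 alone offset this: the number found in shUbc9 was 91.4% of that in shCtrl with SUMO and 89.1% without, and in the 4 parts from the lowest score 87.2% and 85.8%, 92.2% and 85.8%, 88.2% and 89.6%, and 92.7% and 92.6%. Peaks with SUMO were found less often in shCtrl already, 33.8% against 38.6%. A larger net loss of H3K27ac at SUMO peaks after depletion was not shown by these merged lists, which have no replicates.

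The 6 libraries of a comparison can be split in only 10 ways. The real split gave 9051 genes at D4, 9223 at D7, 6986 in ES cells, 16418 between ES and MEF controls, 11152 between D4 and MEF controls and 3057 between D7 and D4 controls, and the highest other count was 0 in each, so 1 of 10 splits was as large. For signature genes it gave 3353 at D4 and 3746 at D7, again with 0 as the highest other and 1 of 10 as large. For gene lists, where camera with a preset correlation was used, the real split gave 9 at D4, 10 at D7 and 9 in ES cells, and the highest other 9, 11 and 10, so that 2, 3 and 3 of 10 were as large and counts of lists were as high in other splits. For repeat families the real split gave 34 at D7 and 60 in ES cells, with 2 and 0 the highest other and 1 of 10 as large. At D4 it gave 3, and another split gave 559, so 2 of 10 were as large, and the cause was not tested.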
